A study of Mus musculus with 4 samples.

How the data were processed

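Gene expression was measured on 4 mouse microarrays, 1 for each of 4 sorted cell populations from bone marrow. The labels describe untreated C57BL/6 mice of 8 weeks, backcrossed for 10 generations or more and kept free of specific pathogens. In the mice used, the coding sequence of green fluorescent protein (GFP) was knocked into the Gfi1 locus, so that GFP reports the activity of Gfi1, a transcriptional repressor of blood cell development. The populations were CD11b-positive, Gr1-low cells of a homozygous knock-in mouse, which lacks Gfi1 (called here Gfi1-deficient monocytes), GFP-high and GFP-low fractions of CD11b-positive, Gr1-low cells of heterozygous knock-in mice (GFP-high and GFP-low monocytes), and CD11b-positive, Gr1-high granulocytes of heterozygous knock-in mice. The names monocyte and granulocyte are those of the labels and rest on the sort.

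Per the labels' protocols, total RNA was extracted with TRIzol, and 6 µg was made into biotin-labelled cRNA by the standard Affymetrix protocol. The values deposited by the authors are on a log2 scale, with 1 value for each of 22690 probe sets on each array. That scale was inferred from the range of the values, which ran from 2.70 to 14.50, and the log base is not stated. The methods of background correction, summarisation and normalization are not given in the sources used here. The array medians were 5.98 for Gfi1-deficient monocytes, 5.96 for GFP-high monocytes, 6.01 for GFP-low monocytes and 5.91 for granulocytes, so the values were taken as already brought to a common distribution and were used without further scaling. Arrays have no read depth, and with 1 array in each group their number limits the precision. Normalization that forces a common distribution would hide a difference that affects most genes in the same direction, and values near the upper end of an array's scale are compressed.

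Probe sets were named from the platform's annotation table, which can be old, updated through gene identifiers to the gene table of the mouse assembly GRCm38.p6, which was used for names, chromosome and neighbouring genes only. Of the 22690 probe sets, 20393 had 1 gene, 691 had several and 1606 had none in the table used. Of those with 1 gene, 20364 were matched by gene identifier and 0 symbols needed an update. No probe set with several genes was used to name a gene, and the 64 control probe sets were kept apart. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 12393 genes, 7437 of them with 1 probe set and 4956 with 2 or more. No genome build is attached to the values, so no coordinates are given.

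The 40th percentile of all values, a log2 value of 5.18, was used as a floor. Values below it were set to it, a difference with 1 array at the floor is given as a bound ("at least"), and no fold is given where both arrays were at the floor. The share of probe sets above the floor was 59.2%, 59.9%, 59.9% and 61.0% on the arrays of Gfi1-deficient monocytes, GFP-high monocytes, GFP-low monocytes and granulocytes. Differences are log2 values of the first population minus the second.

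There are no replicates, so no test was made and no p-value or standard deviation between animals is given. Genes were counted by a rule of size, an absolute log2 difference of 1 or more (2-fold), with 2 or more (4-fold) as a stricter count. The error estimate that the data allow is the scatter between different probe sets of a gene. It was computed over 2981 genes with 2 or more probe sets above the floor as the SD of the difference between the log2 differences of 2 probe sets, divided by the square root of 2. It covers disagreement between probe sets within these arrays and not the spread between animals. It was 0.18 for Gfi1-deficient minus GFP-low monocytes and 0.40 for granulocytes minus GFP-low monocytes. It may therefore also hold real differences between what the probe sets measure, and need not be error alone. RNA quality was read from the control probe sets for Actb and Gapdh as the log2 level at the 3' end minus that at the 5' end. For Actb it was 0.28, 0.16, 0.16 and 0.08 and for Gapdh -0.10, -0.06, -0.06 and -0.06, in the order of arrays given for the floor.

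A total of 24 gene lists were fixed before the data were examined. They were primary granule, secondary and tertiary granule, mature neutrophil, monocyte, macrophage, dendritic cell and MHC class II, myeloid transcription factors, genes known from earlier work as bound or repressed by Gfi1, stem and progenitor, cell cycle, interferon response, immediate early and inflammatory, NADPH oxidase, B cell, T cell, NK cell, erythroid, megakaryocyte and platelet, basophil and mast cell, eosinophil, plasma cell, housekeeping, sex-linked transcripts (X inactivation and Y-linked), and ribosomal proteins. The last list was taken by symbol and so also holds a few kinase genes such as Rps6ka3. Some genes stand in more than 1 list. For each list and comparison the median log2 difference over the members named on the array is given with its percentile among 10000 random lists of the same size, matched on mean log2 value in 20 bins of expression. A percentile of 100 means that the list lay above every random list. Percentiles outside 2.5 to 97.5 are called outside the random range, as a description of these arrays only.

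The genes named in the text follow a rule also fixed then. It takes Gfi1, Cd48, Itgam, Ly6g, Csf1r, Irf8, Cebpe, Mpo and Elane in every array, of which 7 of the 9 had a probe set of their own (Ly6g and Cebpe are not named here). For each comparison it adds the 8 genes with the largest positive and the 8 with the largest negative log2 difference, among genes whose other probe sets above the floor had the same sign, and in each list up to 4 members with the largest absolute difference. Further list members named below were chosen after their values were seen.

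The 5 comparisons were GFP-high minus GFP-low monocytes, granulocytes minus GFP-low monocytes, granulocytes minus GFP-high monocytes, Gfi1-deficient minus GFP-low monocytes and Gfi1-deficient minus GFP-high monocytes. Several share an array and with it that array's error. Correlations across genes were therefore computed for the 3 ways of splitting the 4 arrays into pairs that share no array, beside the overlap expected of independent gene sets (the product of both counts divided by the genes compared). An axis position per gene placed GFP-low monocytes at 0 and granulocytes at 1 on the log2 scale, over genes at least 4-fold apart between those arrays. To weigh carry-over of cells from another population, the share of that population that each gene's level would need was computed on the linear scale, as the excess of the array over a background array divided by that of the source population over the same background.

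The calculation was tested on simulated arrays, each made of the GFP-low values of 12393 genes with added noise of SD 0.2. Known changes were put into the simulated GFP-high array, which was compared with the simulated GFP-low array. Only genes well above the floor were changed, so the recovery does not describe genes near it. Of 100 genes changed by a log2 value of 1.5, 97.0% were recovered, and of 100 genes changed by 3.0, 100.0%. The rule of size called 5 unchanged genes. The simulated noise was 1 fixed value and held no spread between animals. On the real arrays the scatter between probe sets ran from 0.18 to 0.40 over the 5 comparisons. The 5 genes are therefore no estimate of false calls in the real comparisons. A list of changed genes lay at percentile 100, and 1 of 40 lists of unchanged genes lay outside the random range. Alternatives were floors at the 20th and 60th percentile, quantile normalization, the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at (which can match several transcripts or genes), leaving out list members at the floor, and axis genes at 2-fold. Counts without genes of the X and Y chromosomes were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.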

Results

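Expression profiles of 4 sorted bone marrow populations were compared, with 1 array each. The series addresses the role of Gfi1 in the choice between the monocytic and the granulocytic lineage, with the surface protein CD48 as a marker. Of 12393 named genes, 8621 were above the floor on at least 1 array, with 7787 on the array of Gfi1-deficient monocytes, 7922 on that of GFP-high monocytes, 7901 on that of GFP-low monocytes and 8128 on that of granulocytes. Because no population was measured more than 1 time, every value below describes these arrays and has no replicate check. Across the 8621 genes, which are not independent replicates, Gfi1-deficient and GFP-low monocytes had the highest correlation of any pair of arrays (Pearson's r = 0.980). GFP-high monocytes correlated with Gfi1-deficient monocytes at 0.865, with GFP-low monocytes at 0.857 and with granulocytes at 0.847. Granulocytes correlated with GFP-low monocytes at 0.815 and with Gfi1-deficient monocytes at 0.784.

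The Gfi1 probe set read log2 10.31 in GFP-high monocytes, 7.31 in granulocytes, 5.18 in Gfi1-deficient monocytes and 3.74 in GFP-low monocytes, the last 2 being below the floor. The order of the GFP-high and GFP-low arrays followed their reporter labels, with Gfi1 at least 35.1-fold higher in GFP-high monocytes. Whether this probe set lies in the part of the gene replaced by GFP is not known here, so its level in Gfi1-deficient monocytes does not check that label. Cd48, which encodes the CD48 surface protein, read 11.22 in GFP-low and 10.98 in Gfi1-deficient monocytes against 7.78 in GFP-high monocytes and 7.10 in granulocytes. Csf1r, the receptor for macrophage colony-stimulating factor, read 12.90 in GFP-low, 12.62 in Gfi1-deficient and 8.86 in GFP-high monocytes and 10.99 in granulocytes. Irf8, a transcription factor of monocyte development, read 10.80 in both GFP-low and Gfi1-deficient monocytes, 7.09 in GFP-high monocytes and 7.23 in granulocytes. Itgam, which encodes the CD11b chain used in the sort, was high on each array, from 10.28 in GFP-low monocytes to 11.92 in granulocytes. The array of Gfi1-deficient monocytes stood apart in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, read 5.80 there against 10.42 in GFP-low monocytes, 10.93 in GFP-high monocytes and 9.56 in granulocytes, while the Y-linked Eif2s3y read 8.31 there and was below the floor on the other arrays.

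**Figure D1:**
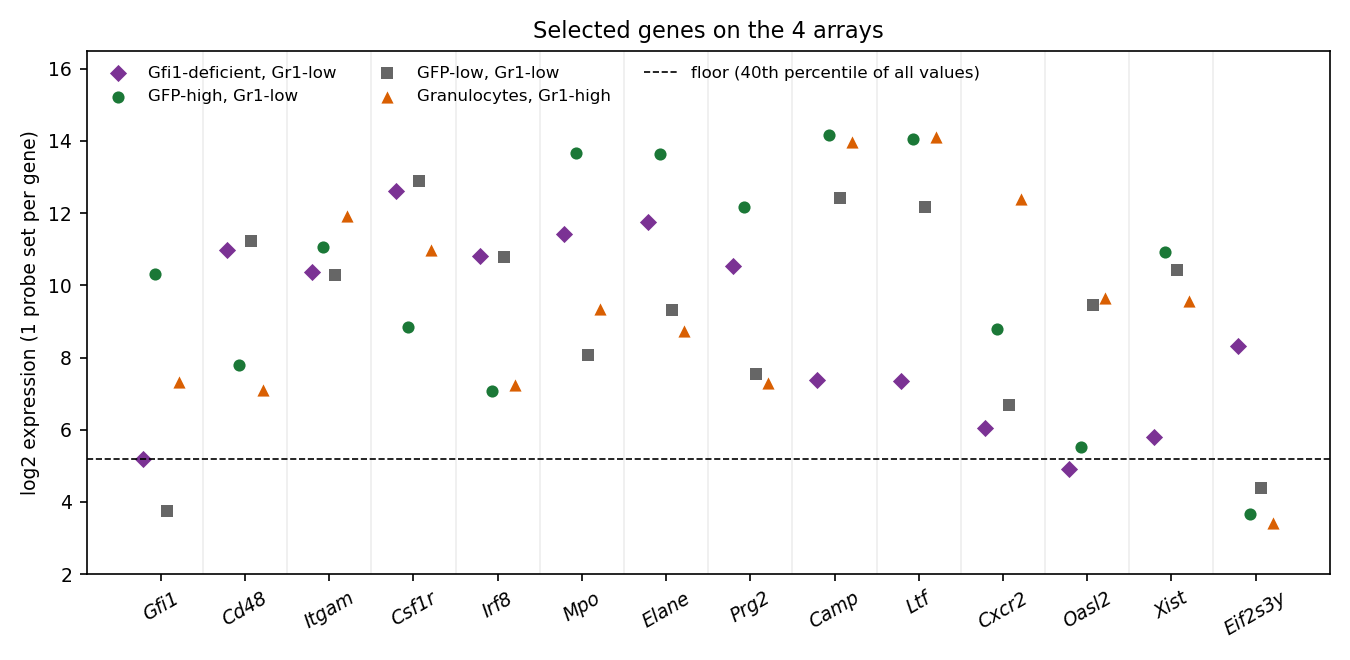
Log2 expression (vertical axis) of 14 selected genes (horizontal axis) on the 4 arrays, with 1 symbol per array and a dashed line at the floor of 5.18. Cd48, Csf1r and Irf8 lie close together in GFP-low and Gfi1-deficient monocytes, Camp reads 7.37 in Gfi1-deficient monocytes against 12.41 to 14.18 on the other arrays, and Xist and Eif2s3y set the array of Gfi1-deficient monocytes apart.

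GFP-high and GFP-low monocytes, which share genotype and Gr1 gate, were compared to see what goes with the level of the reporter. Primary granule genes, most of which encode proteases or the peroxidase of early neutrophil granules, were at least 2-fold higher in GFP-high monocytes for 6 of 7 members. Their median log2 difference of 4.32 lay above all 10000 random lists. Ms4a3, a marker of granulocyte-monocyte progenitors, was 86.3-fold higher, Mpo, which encodes myeloperoxidase, was 48.0-fold higher, and Elane, which encodes neutrophil elastase, had a log2 difference of 4.32. The remaining member, Ctsc, whose product activates these proteases, was 9.30-fold lower. Monocyte genes were at least 2-fold lower in GFP-high monocytes for 18 of 19 members, with a median of -4.25 below all random lists. S100a4, a calcium-binding protein, was 69.0-fold lower, Ccr2, the chemokine receptor for monocyte exit from bone marrow, was 47.2-fold lower, and Csf1r was 16.4-fold lower. Cd48 was 10.9-fold lower, Irf8 13.1-fold lower and Itgam 1.72-fold higher. Secondary and tertiary granule genes were at least 2-fold higher for 12 of 15 members (median 1.72, percentile 100), among them the integrin gene Itgb2l with a log2 difference of 4.42 and the gelatinase gene Mmp9 with 2.80. Cell cycle genes were at least 2-fold higher for 19 of 26 members (median 1.23, percentile 100), led by Rrm2, a subunit of ribonucleotide reductase, with 1.93. Mature neutrophil genes went both ways, with 6 of 14 members at least 2-fold higher and 4 at least 2-fold lower (median 0.68, percentile 99.91). Il1r2, a decoy receptor for interleukin-1, had a log2 difference of 3.16 and the chemokine gene Ccl6 one of -2.46.

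Further genes with the largest differences between GFP-high and GFP-low monocytes were, on the higher side, Prom1 (at least 58.9-fold), a surface protein of progenitor cells, the granule membrane protein gene Nkg7 (48.2-fold), the acute-phase protein gene Orm1 (35.3-fold), Gca, which encodes grancalcin (34.7-fold), and the transcription factor gene Klf5 (32.2-fold). On the lower side were Ms4a4c (51.1-fold), the interferon-inducible Ifi209 (40.5-fold), the calpain subunit gene Capn2 (39.7-fold), the receptor phosphatase gene Ptpro (39.6-fold), Ms4a6b (35.0-fold) and the chemokine gene Ccl9 (34.9-fold). Interferon response genes were at least 2-fold lower in GFP-high monocytes for 13 of 14 members (median -2.09, below all random lists), with Oasl2, of the oligoadenylate synthetase family, at -3.94 and the deubiquitinase gene Usp18 at -3.78. Immediate early and inflammatory genes were at least 2-fold lower for 9 of 17 measured members and higher for 2 (median -1.03, percentile 0), with the stress-induced transcription factor gene Atf3 at -5.09 and the chemokine gene Ccl3 at -4.22. Genes of the NADPH oxidase, the enzyme of the respiratory burst, were at least 2-fold higher for 2 of 5 members (median 0.99, percentile 99.5), Ncf1 with 1.87 and Ncf4 with 1.23. In all, 743 of 8232 genes above the floor were at least 2-fold higher and 791 at least 2-fold lower in GFP-high monocytes, and 204 and 282 at least 4-fold. Probe sets of the same gene differed with an SD of 0.33, and for 572 of 583 genes at least 2-fold apart with several probe sets these had the same sign.

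**Figure D2:**
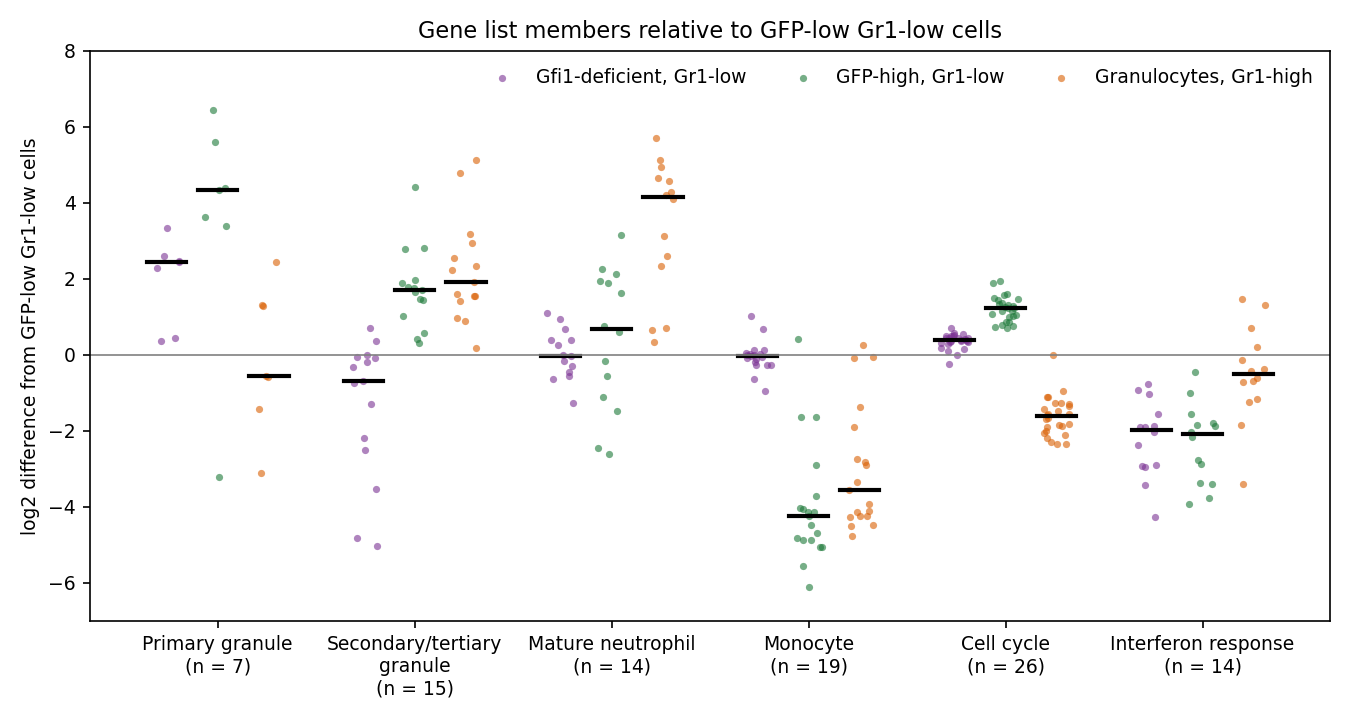
Log2 difference from GFP-low monocytes (vertical axis) for the members of 6 gene lists (horizontal axis, n members each) in Gfi1-deficient monocytes, GFP-high monocytes and granulocytes. Each point is 1 gene and each black bar a list median. Primary granule genes have a median of 4.32 in GFP-high and 2.44 in Gfi1-deficient monocytes, and monocyte genes a median of -4.25 in GFP-high monocytes, -3.57 in granulocytes and -0.03 in Gfi1-deficient monocytes.

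Granulocytes and GFP-low monocytes set the range between the lineages in heterozygous mice. Mature neutrophil genes were at least 2-fold higher in granulocytes for 11 of 14 members, with a median log2 difference of 4.15 above all random lists. Cxcr2, the chemokine receptor for neutrophil recruitment, was 52.5-fold higher, and Il1r2 had a log2 difference of 5.13. Secondary and tertiary granule genes were at least 2-fold higher for 12 of 15 members (median 1.92, percentile 100), with Mmp9 at 5.14 and Itgb2l at 4.78. Primary granule genes went both ways, 3 of 7 members being at least 2-fold higher and 2 lower (median -0.55, percentile 14.6). Mpo was 2.42-fold higher, and Elane was lower by 1.51-fold, under the 2-fold rule. Monocyte genes were at least 2-fold lower in granulocytes for 16 of 19 members (median -3.57, percentile 0), with S100a4 27.1-fold, the fibronectin gene Fn1 22.9-fold and Csf1r 3.75-fold lower. Cd48 was 17.4-fold lower, Irf8 11.9-fold lower, Itgam 3.10-fold higher and Gfi1 at least 4.38-fold higher. Cell cycle genes were at least 2-fold lower for 24 of 25 measured members (median -1.62, percentile 0), among them the mitotic kinase gene Bub1 at -2.34. Mcm3, a helicase subunit of DNA replication at -2.12, had other probe sets of a different sign.

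The largest differences on the granulocyte side also included Ceacam10 (65.2-fold), Arg2, which encodes mitochondrial arginase (at least 63.1-fold), the interleukin-1 family gene Il1f9 (53.9-fold), Ankrd33b (at least 46.6-fold), Scrg1 (44.7-fold), the protease gene Asprv1 (43.0-fold) and the actinin gene Actn1 (37.5-fold). On the GFP-low side they included Capn2 (42.7-fold), the lectin receptor gene Cd302 (at least 25.5-fold), Ptpro (22.3-fold), Ms4a6d (at least 22.2-fold), the peroxiredoxin gene Prdx4 (20.3-fold) and the phosphatase gene Dusp3 (20.2-fold). NADPH oxidase genes were at least 2-fold higher in granulocytes for 3 of 5 members (median 1.13, percentile 98.8). Immediate early and inflammatory genes were at least 2-fold higher for 6 of 17 measured members and lower for 3 (median 0.46, percentile 99.0), with the interleukin gene Il1b at 4.64 and Atf3 at -3.02. Interferon response genes had a median of -0.51 (percentile 10.0), with 2 of 14 members at least 2-fold higher and 4 lower. With the floor at the 60th percentile the interferon median was -0.40 and lay outside the random range (percentile 0.46). In all, 852 of 8503 genes were at least 2-fold higher in granulocytes and 1550 lower, and 284 and 378 at least 4-fold. The SD between probe sets of a gene was 0.40, and 917 of 977 genes at least 2-fold apart had probe sets of the same sign.

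Granulocytes were also compared with GFP-high monocytes, which differ from them in Gr1. Primary granule genes were at least 2-fold lower in granulocytes for 5 of 7 members (median -4.91, below all random lists), Ms4a3 by 35.0-fold, the proteinase 3 gene Prtn3 by 33.5-fold, the cathepsin G gene Ctsg by 30.4-fold, Elane by 30.1-fold and Mpo by 19.8-fold. Cell cycle genes were at least 2-fold lower for 25 of 26 members (median -2.82, percentile 0), with the helicase subunit gene Mcm5 at -3.80. Mature neutrophil genes were at least 2-fold higher in granulocytes for 11 of 14 members (median 2.66, percentile 100), including the lectin receptor gene Clec4d (54.4-fold), Il1b (54.0-fold) and the cyclooxygenase gene Ptgs2 (at least 52.8-fold). Secondary and tertiary granule genes lay within the random range (median 0.14, percentile 62.5), with 3 of 15 members at least 2-fold higher, Mmp9 at 2.34, the collagenase gene Mmp8 at 2.23 and Padi4, which encodes an enzyme of histone citrullination, at 1.46. Some members read near the top of the scale on both arrays, such as Ltf (14.10 in granulocytes, 14.07 in GFP-high monocytes) and Camp (13.96 and 14.18). Compression there may hide differences. Monocyte genes were at least 2-fold higher in granulocytes for 9 of 18 measured members (median 0.94, percentile 99.99), including Csf1r (4.39-fold). Cd48 was 1.60-fold lower, Irf8 1.10-fold higher and Itgam 1.81-fold higher, all under the 2-fold rule, and Gfi1 was 8.00-fold lower.

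Interferon response genes were at least 2-fold higher in granulocytes than in GFP-high monocytes for 9 of 13 measured members (median 2.07, percentile 100), Oasl2 by 4.15 and Rsad2, an antiviral enzyme gene, by 3.35. Immediate early and inflammatory genes were at least 2-fold higher for 10 of 17 (median 1.66, percentile 100), with the chemokine gene Cxcl2 at 4.27. NADPH oxidase genes had a median of 0.09 (percentile 53.6). Other large differences on the granulocyte side were Arg2 (at least 63.1-fold), the surface enzyme gene Bst1 (30.9-fold), H2-Q10, of the MHC class I family (at least 30.4-fold), Ankrd33b (29.5-fold) and the peptide transporter gene Slc15a3 (29.0-fold). On the GFP-high side were Epx, which encodes eosinophil peroxidase (at least 32.0-fold), Nkg7 (30.3-fold), the cystatin gene Cst7 (at least 29.7-fold) and Prg2, which encodes eosinophil major basic protein (29.3-fold). In all, 755 of 8457 genes were at least 2-fold higher and 1383 lower in granulocytes, and 208 and 375 at least 4-fold. The SD between probe sets was 0.37, and 819 of 870 genes had probe sets of the same sign.

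Gfi1-deficient monocytes were compared with GFP-low monocytes to see how the loss of Gfi1 goes with the expression of Gr1-low cells. The sample label of the Gfi1-deficient cells names no GFP gate. Genotype and sort therefore differ together in this comparison and in that with GFP-high monocytes. Gfi1 read below the floor in both, at 5.18, just under it, in Gfi1-deficient and 3.74 in GFP-low monocytes. No fold is given, and how far these arrays differ in the Gfi1 level cannot be told from this probe set. Monocyte genes were at similar levels, with a median log2 difference of -0.03 (percentile 13.9) and 1 of 19 members, Ms4a6d at 1.01, at least 2-fold apart. Cd48 was 1.19-fold lower, Csf1r 1.22-fold lower, and Irf8 and Itgam were within 1.07-fold, all under the 2-fold rule. Primary granule genes were at least 2-fold higher in Gfi1-deficient monocytes for 5 of 7 members (median 2.44, percentile 100), with Mpo 10.1-fold, Ms4a3 6.05-fold, Ctsg 5.53-fold and Elane 5.42-fold higher. Secondary and tertiary granule genes were at least 2-fold lower for 6 of 15 members and higher for 0 (median -0.68, percentile 0). Among them Camp, the cathelicidin gene, was 32.9-fold, Ltf, the lactoferrin gene, 28.2-fold and the neutrophilic granule protein gene Ngp 11.5-fold lower, and Mmp9 was at -2.52. Camp, Ltf and Ngp read 12.41, 12.18 and 13.32 in GFP-low monocytes. The array of Gfi1-deficient monocytes also differed in Xist, which was 24.6-fold lower, and in the Y-linked genes Eif2s3y (at least 8.75-fold higher) and Kdm5d (log2 6.08, below the floor on the other arrays). Uty, the remaining gene of the list of sex-linked transcripts, was below the floor throughout, and the list median was 0.45. Mature neutrophil genes lay within the random range (median -0.02, percentile 19.6), with Ifitm1, an interferon-induced membrane protein gene, at 1.10 and S100a9, a subunit of calprotectin, at -1.28.

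Interferon response genes were at least 2-fold lower in Gfi1-deficient than in GFP-low monocytes for 12 of 14 members (median -1.97, below all random lists). Oasl2 was at least 19.3-fold lower, and Ifit3 and Ifit2, antiviral genes of the tetratricopeptide family, were 10.7-fold and 7.82-fold lower. Cell cycle genes were higher by a median of 0.39 (percentile 100), with 0 of 25 measured members reaching 2-fold and the mitotic kinase gene Aurka at 0.69. Immediate early and inflammatory genes had a median of -0.22 (percentile 0), with 1 of 17, the early response gene Ier3 at 1.93, at least 2-fold apart, and NADPH oxidase genes one of -0.03 (percentile 33.8). Genes known from earlier work as bound or repressed by Gfi1 had a median of -0.04 (percentile 5.28), with 1 of 14 measured members, the transcription factor gene Ets1, lower by at least 2.21-fold. This list lay below the random range under 3 alternatives, with -0.14 for the floor at the 20th percentile, -0.086 for quantile normalization and -0.14 without members at the floor. Further genes with the largest differences were the skin-secreted factor gene Dmkn (at least 12.1-fold), the glycoprotein gene Lrg1 (8.45-fold), Prg2 (8.03-fold), Epx (at least 7.63-fold) and the acute-phase gene Saa3 (6.87-fold) on the higher side, and Igha, the immunoglobulin A heavy chain gene (9.66-fold), on the lower side. In all, 51 of 8010 genes were at least 2-fold higher and 102 lower, and 14 and 23 at least 4-fold. Without genes of the X and Y chromosomes, an alternative added after the data were seen, the counts were 50 and 100. The SD between probe sets was 0.18, and 40 of 42 genes had probe sets of the same sign.

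The comparison of Gfi1-deficient with GFP-high monocytes sets cells that lack Gfi1 beside the Gr1-low cells with the highest Gfi1 reading. Monocyte genes were at least 2-fold higher in Gfi1-deficient monocytes for 18 of 19 members (median 4.11, percentile 100), with S100a4 69.5-fold, Ccr2 47.5-fold, Csf1r 13.5-fold and Irf8 13.1-fold higher. Cd48 was 9.19-fold higher, Itgam 1.60-fold lower and Gfi1 at least 35.1-fold lower. Secondary and tertiary granule genes were at least 2-fold lower for 12 of 15 members (median -2.34, percentile 0), with Camp 112-fold, Ltf 105-fold, Itgb2l 98.1-fold and Mmp9 39.8-fold lower. Primary granule genes were at least 2-fold lower for 6 of 7 members (median -1.91, percentile 0), Mpo by 4.75-fold and Elane by 3.69-fold. Mature neutrophil genes were at least 2-fold lower for 8 of 14 members and higher for 4 (median -1.03, percentile 0). Cell cycle genes were at least 2-fold lower for 10 of 26 members (median -0.85, percentile 0), with Rrm2 at -1.42, and NADPH oxidase genes for 2 of 5 (median -0.90, percentile 0.65). Immediate early and inflammatory genes were at least 2-fold higher for 10 of 17 measured members (median 1.21, percentile 100), with Atf3 27.9-fold higher. Interferon response genes lay within the random range (median 0.04, percentile 65.7), with 2 of 13 measured members higher and 2 lower. Xist differed by -5.13 between these arrays, and the median of the sex-linked list was again 0.45, against 0.00 in the 3 comparisons among heterozygous populations. Other large differences were Capn2 (49.0-fold), Ms4a4c (46.6-fold), Ms4a6d (at least 44.9-fold), Dusp3 (39.0-fold), Cd302 (37.2-fold) and Ccl9 (35.2-fold) on the higher side, and Prom1 (at least 58.9-fold), Orm1 (at least 48.9-fold), Klf5 (at least 46.8-fold) and Actn1 (38.8-fold) on the lower side. In all, 781 of 8195 genes were at least 2-fold higher in Gfi1-deficient monocytes and 640 lower, and 242 and 197 at least 4-fold. Without genes of the X and Y chromosomes the counts were 759 and 625. The SD between probe sets was 0.33, and 536 of 551 genes had probe sets of the same sign.

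Where the Gr1-low populations lie between GFP-low monocytes (0) and granulocytes (1) was described over genes at least 4-fold apart between those arrays. GFP-high monocytes had a median position of 0.58 over the 284 genes higher in granulocytes, with an interquartile range of 0.27 to 0.89, and of 0.56 over the 378 genes higher in GFP-low monocytes, with a range of 0.11 to 1.00. The latter value moved to 0.84 with the floor at the 60th percentile and to 0.22 with axis genes at 2-fold. Positions of GFP-high monocytes differed between gene groups, with medians of 0.93 for 12 secondary and tertiary granule genes, 0.37 for 11 mature neutrophil genes, 1.23 for 16 monocyte genes and -0.66 for 24 cell cycle genes, over members at least 2-fold apart. Compression near the top of the scale may bear on the value for secondary and tertiary granule genes. Gfi1-deficient monocytes had median positions of 0.00 (interquartile range -0.10 to 0.08) and -0.05 (-0.12 to 0.07) over the same 284 and 378 genes. Their list medians also differed, for example -0.37 over the secondary and tertiary granule genes and 0.01 over 16 monocyte genes. For 7 dendritic cell and MHC class II genes the median was 1.05 (0.56 to 1.21). For 6 interferon response genes it was 0.60 (-0.76 to 1.13).

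In comparisons that share no array, the difference of GFP-high minus Gfi1-deficient monocytes correlated across 8621 genes with that of granulocytes minus GFP-low monocytes (Pearson's r = 0.58, Spearman's rho = 0.48). Of the genes at least 2-fold higher, 360 were shared, against 63.3 for independent sets, and of those lower 452 were shared, against 140. Genes are not independent replicates, so no p-value is attached. The second of the 3 splits, Gfi1-deficient minus GFP-low monocytes against granulocytes minus GFP-high monocytes, gave an r of -0.35 and a rho of -0.42. The last, GFP-high minus GFP-low monocytes against granulocytes minus Gfi1-deficient monocytes, gave an r of 0.41 and a rho of 0.28.

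**Figure D3:**
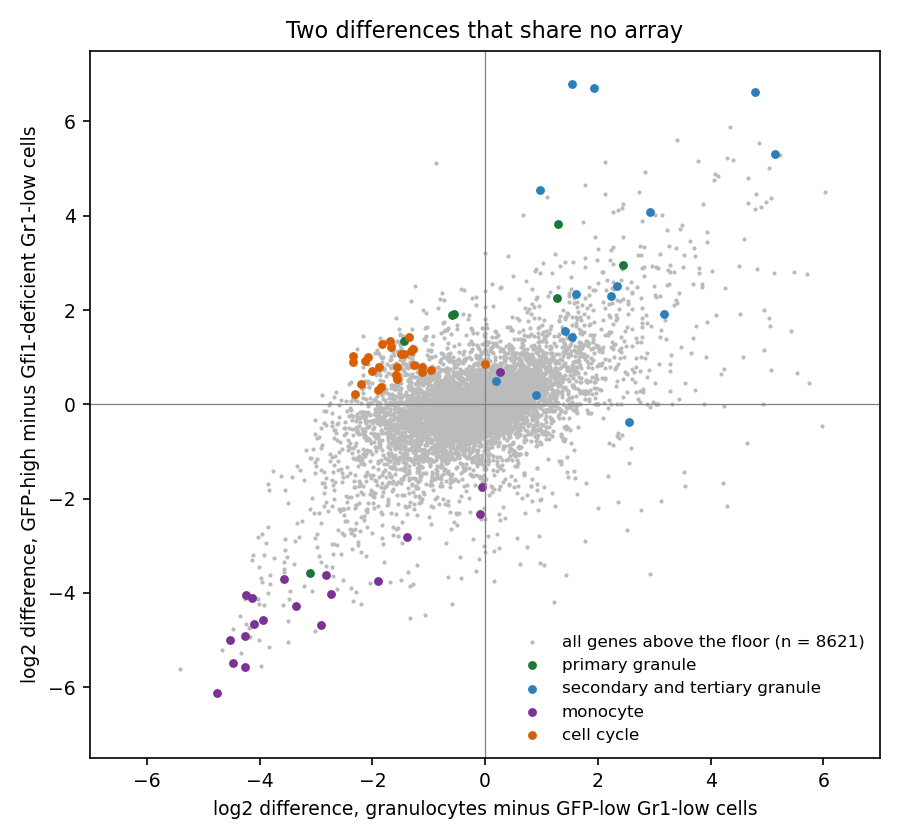
Log2 difference of GFP-high minus Gfi1-deficient monocytes (vertical axis) against that of granulocytes minus GFP-low monocytes (horizontal axis) for 8621 genes, with members of 4 lists coloured. Across genes r is 0.58, and cell cycle genes lie to the left of 0 on the horizontal axis and above 0 on the vertical axis, except for Tyms at 0 on the horizontal axis.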

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

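All tests weighed in this part were chosen only after the result was seen. Signals outside the main measurement came from control probe sets and from probe sets that carry no gene name of their own. The hybridization controls, bacterial and phage transcripts added at a set amount, differed from the array of GFP-low monocytes by a median log2 value of -0.13 in Gfi1-deficient monocytes, 0.39 in GFP-high monocytes and 0.29 in granulocytes. The poly-A controls, transcripts usually added before labelling, differed by 0.16, 0.30 and 0.95 in the same order. Of 2246 probe sets without a gene name of their own, 182 were at least 2-fold apart between GFP-high and GFP-low monocytes, 367 between granulocytes and GFP-low monocytes, 339 between granulocytes and GFP-high monocytes, 35 between Gfi1-deficient and GFP-low monocytes and 193 between Gfi1-deficient and GFP-high monocytes.

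The first pattern is the profile of GFP-high monocytes, with granule genes high and monocyte genes low in a gate labelled monocytes. A mixture of GFP-low monocytes and granulocytes cannot exceed both sources, yet 24 primary granule and cell cycle members lay at least 2-fold above both arrays, 5 of 7 and 19 of 26. Labelling or hybridization that differed for transcripts in general is argued against, since no control probe set differed by more than 0.54 between these arrays, while the primary granule and monocyte medians were 4.32 and -4.25. Eosinophil genes were also higher (median 2.96, Prg2 24.7-fold), and macrophage genes went both ways, with Vcam1 24.1-fold and Cd5l 5.59-fold higher, Cd68 14.4-fold and Adgre1 5.37-fold lower, and a median of 0 with the floor at the 60th percentile. A candidate explanation is that the gate holds proliferating granulocytic precursors, a hypothesis found on the same arrays that does not account for each of these genes and was not tested further.

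The second pattern is the low level of interferon response genes in both Gfi1-deficient and GFP-high monocytes, while granulocytes lay at a median of -0.51 from GFP-low monocytes. Argued against are animal sex for GFP-high monocytes, by Xist, which lay 5.13 log2 units above that of Gfi1-deficient monocytes, and a general labelling difference by control probe sets, which differed from GFP-low monocytes by at most 0.54 on either array against interferon medians of -1.97 and -2.09. For Gfi1-deficient monocytes, genotype, sex and the sort cannot be told apart. Xist differed by -4.62 on the only array of that genotype, and its label names no GFP gate. Exposure to interferon that differed between animals or preparations also stays open, because 1 array per group gives no spread between animals. The genes were low both where Gfi1 read highest (10.31, GFP-high) and in cells that lack it. They were high in GFP-low monocytes, where Gfi1 was below the floor. These arrays also differ in their cells, as do granulocytes (Gfi1 at 7.31), so this order cannot decide on an effect of the Gfi1 level. Both low medians are measured against the same GFP-low array. An effect behind either part alone was not tested.

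The third pattern is the granule genes of Gfi1-deficient monocytes relative to GFP-low monocytes, primary ones high and secondary ones low. Carry-over of cells like the GFP-high array was weighed for the primary granule genes. The 26 other genes at least 16-fold higher in GFP-high than in GFP-low monocytes implied a median share of -1.24% (quartiles -2.17% and 0.66%). A negative share means that a gene read lower in Gfi1-deficient than in GFP-low monocytes, the background array. The 6 primary granule members at least 2-fold higher in GFP-high than in GFP-low monocytes implied 21.1% (quartiles 9.29% and 23.2%). However, 4 of the 26, Lrg1 (41.7%), Prg2 (29.6%), Epx (22.1%) and Cst7 (14.6%), also lay above that lower quartile. Mpo read 13.66 in GFP-high monocytes, so compression near the top of the scale may also raise the shares of primary granule members. The shares of both gene groups argue against cells with the full profile of the heterozygous GFP-high array only. Counterparts of such cells in a mouse that lacks Gfi1 need not express all 26 genes, Gfi1 itself being among them. The shares cannot decide on such counterparts. For the low secondary granule genes, Mmp9 would need 2.36% and Itgb2l 2.87% granulocytes in the GFP-low sort, against a median of 1.35% (quartiles 0.37% and 2.69%) from 51 other genes, so carry-over may account for this part, a split of the 6 low genes made after seeing their values. Camp, Ltf, Ngp and Pglyrp1 would need at least 8.19%. Their granulocyte levels, from 13.67 upwards, like that of Mmp9 (13.59), exceed the 13.07 that the comparison genes reach. Compression near the top of the scale therefore stays open as the reason, and the low share from Mmp9, 1 gene, cannot decide it. All these shares take Gr1-high granulocytes as the source. In GFP-high monocytes Camp read 14.18 but Mmp9 11.25, so the 2 genes need not go together in other cells. Carry-over of other cells into the GFP-low sort was not weighed. Animal sex (Xist at -4.62) and a sort whose label names no GFP gate remain open. So do cells with only part of the GFP-high profile, such as early precursors that lack Gfi1, and an effect of Gfi1 on these genes. These cannot be told apart here.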

How the results depend on the processing

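Counts without genes of the X and Y chromosomes were chosen after the data were seen; all other alternatives were planned. No replicate could be left out, since each group has 1 array. No paired analysis was possible because each group has 1 array and no result comes from a test. Under those of the 8 alternatives that apply to it, no called value reversed direction. Axis genes at 2-fold and leaving out members at the floor do not bear on gene counts, and the X and Y alternative was run for the Gfi1-deficient comparisons only. The counts of genes at least 2-fold apart stayed within 1.5 times of the main ones, for example 34 to 62 higher and 69 to 113 lower in Gfi1-deficient against GFP-low monocytes, and 579 to 794 and 597 to 841 in GFP-high against GFP-low monocytes. The position of GFP-high monocytes over genes higher in GFP-low monocytes moved from 0.56 to 0.84 with the floor at the 60th percentile and to 0.22 with axis genes at 2-fold. Of 120 list medians, 9 moved out of the random range and 18 into it under 1 alternative or more. Below, H, L, K and G stand for GFP-high, GFP-low and Gfi1-deficient monocytes and granulocytes. With the floor at the 60th percentile, medians of 0 within the random range were found for macrophage (H-L, G-H, K-L, K-H), dendritic cell (G-H), Gfi1-bound (G-L), stem (K-L), B cell (G-L, K-L), NK, erythroid and basophil (K-L) and sex-linked genes (K-L, K-H). At that floor, myeloid transcription factors (G-H) had 0.07, also within it, and interferon response (G-L, -0.40) and plasma cell (H-L, -0.14) lay outside it. With the floor at the 20th percentile, stem (K-L, -0.093) and ribosomal genes (H-L, -0.14, and K-L, 0.10) lay within the range, and Gfi1-bound (K-L, -0.14), T cell (K-H, -0.27), NK (H-L, -0.25) and plasma cell genes (H-L, -1.23, K-L, -0.65, and K-H, 0.58) outside it. With the mean of all probe sets, myeloid transcription factors (G-H, 0.25), Gfi1-bound (G-L, 0.24), ribosomal (H-L, -0.13, and K-L, 0.084) and, at 0, stem, B and NK cell (K-L) and sex-linked genes (K-L, K-H) lay within it, and erythroid genes (H-L, -0.35) outside it. Without members at the floor, Gfi1-bound (G-L, 0.46), sex-linked (K-H, 0.91) and ribosomal genes (H-L, -0.17, K-L, 0.10, and K-H, 0.25) lay within it, and Gfi1-bound (K-L, -0.14), T cell (G-H, 0.58) and plasma cell genes (K-L, -0.56) outside it. Quantile normalization moved Gfi1-bound genes (K-L, -0.086) out, and leaving out _x_at and _s_at probe sets moved B cell genes (K-L, 0) in. Apart from interferon response in granulocytes, no call moved for the granule, mature neutrophil, monocyte, cell cycle and interferon lists. A higher floor sets more members to it, which gives medians of 0; for the other changes the cause was not tested. Of 111 differences of named genes, 56 moved by more than the scatter between probe sets under at least 1 alternative, and 3 could not be given without _x_at and _s_at probe sets. Levels near the floor limit low genes, and compression near the top of the scale limits the brightest.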

Other observations

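The test of sex-linked escape genes and that of the neighbours of Gfi1 were written before their results were seen, and the count of lowered neighbours after; the groups and genes described here without a test were picked after their values were seen. In GFP-high monocytes 5 of 6 measured eosinophil genes were at least 2-fold above GFP-low monocytes (median log2 difference 2.96, percentile 100), with Epx at least 32.0-fold higher and Prg2 at 4.63. In Gfi1-deficient monocytes 4 of 5 were at least 2-fold above GFP-low monocytes (median 1.05, percentile 100), and against GFP-high monocytes the median was -1.74. In granulocytes the median was 0.00 against GFP-low and -3.53 against GFP-high monocytes. Macrophage genes split in GFP-high against GFP-low monocytes, with 5 of 14 measured members at least 2-fold higher and 3 lower (median 0.54, percentile 100). Vcam1, an adhesion molecule, was at 4.59, Cd5l, a secreted macrophage protein gene, at 2.48 and the complement genes C1qa and C1qc both at 2.30, whereas the lysosomal membrane protein gene Cd68 was at -3.85 and Adgre1, a macrophage surface receptor gene, at -2.42. The macrophage medians were 0.00 for granulocytes against GFP-low monocytes, -0.56 for granulocytes against GFP-high monocytes, -0.07 for Gfi1-deficient against GFP-low monocytes and -0.66 for Gfi1-deficient against GFP-high monocytes. With the floor at the 60th percentile these medians were 0.

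Of dendritic cell and MHC class II genes, 7 of 10 measured members were at least 2-fold lower than in GFP-low monocytes in GFP-high monocytes (median -2.31, percentile 0), 7 of 10 in granulocytes (median -1.17, percentile 0.01) and 5 of 10 in Gfi1-deficient monocytes (median -0.58, percentile 0). Itgax, an integrin gene of dendritic cells, was 1.91-fold higher in granulocytes. In Gfi1-deficient monocytes the class II genes H2-Aa and H2-Ab1 were at -1.97 and -1.93, and Cd74, the invariant chain gene, at -1.81. The median was 0.33 for granulocytes and 0.95 for Gfi1-deficient monocytes against GFP-high monocytes. Ribosomal protein genes were lower in granulocytes, with 29 of 45 measured members at least 2-fold below GFP-low monocytes (median -1.13) and 23 of 44 below GFP-high monocytes (median -0.97), both below all random lists and in the same direction after quantile normalization. The poly-A controls of granulocytes lay above those of GFP-low monocytes by a median of 0.95 (range 0.47 to 1.27), a shift of similar size in the other direction, and housekeeping genes by 0.08; whether the controls bear on the granulocyte differences was not tested. The ribosomal medians were -0.14 for GFP-high against GFP-low monocytes, 0.09 for Gfi1-deficient against GFP-low and 0.24 for Gfi1-deficient against GFP-high monocytes.

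Among myeloid transcription factors, medians lay between -0.10 and 0.35 in the 5 comparisons while members went both ways. In GFP-high against GFP-low monocytes 5 of 20 measured members were at least 2-fold higher and 8 lower, with Myb, a factor of progenitor proliferation, at 3.25 and Klf4, a factor of monocyte differentiation, at -4.68. Genes known from earlier work as bound or repressed by Gfi1 had medians of 0.00 for GFP-high against GFP-low monocytes, 0.46 (percentile 99.6) and 0.21 for granulocytes against GFP-low and GFP-high monocytes, and -0.03 for Gfi1-deficient against GFP-high monocytes. The median of 0.46 lay within the random range under 3 alternatives, being 0 with the floor at the 60th percentile, 0.24 with the mean of all probe sets and 0.46 without members at the floor. Ets1 was at 4.01 in GFP-high against GFP-low monocytes and the cell cycle inhibitor gene Cdkn1a at -2.31. Stem and progenitor genes had medians of 0.00 in the 3 comparisons among heterozygous populations, -0.09 for Gfi1-deficient against GFP-low and -0.06 for Gfi1-deficient against GFP-high monocytes, with the stem cell factor receptor gene Kit at 2.94 or more in GFP-high against GFP-low monocytes.

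Markers of other cell types that a bone marrow sort can hold were described in the same way. In the order GFP-high minus GFP-low monocytes, granulocytes minus GFP-low, granulocytes minus GFP-high, Gfi1-deficient minus GFP-low and Gfi1-deficient minus GFP-high monocytes, the list medians were -0.03, 0.72, 0.83, -0.05 and 0.00 for B cell genes, 0.00 throughout for T cell genes, and 0.00, 0.10, 0.09, -0.04 and 0.00 for NK cell genes. They were -0.35, 0.55, 1.02, -0.68 and -0.33 for erythroid genes, 0.00, 0.13, 0.09, -0.02 and -0.10 for megakaryocyte and platelet genes, 0.00, 0.00, 0.00, -0.62 and -0.20 for basophil and mast cell genes, and -0.14, -1.0, 0.00, -0.05 and 0.28 for plasma cell genes. Housekeeping genes had 0.10, 0.08, -0.04, -0.06 and -0.09, of which the third was 0.06 after quantile normalization. Outside the random range were the 2 granulocyte comparisons for B cell and erythroid genes, granulocytes against GFP-low monocytes for plasma cell genes, and Gfi1-deficient against GFP-low monocytes for B cell, NK cell, erythroid and basophil and mast cell genes. With the floor at the 60th percentile the last 4 of these and the B cell median of granulocytes against GFP-low monocytes were 0. Granulocytes were at least 2-fold above GFP-low monocytes in 4 of 8 measured B cell genes, among them the pre-B cell genes Vpreb3 (1.34) and Vpreb1 (at least 1.04). The B cell genes Ebf1 and Pax5 were below the floor on each array. Of 4 measured T cell genes 1 was, the T cell receptor subunit gene Cd3d, at least 3.30 above. Hdc, the histidine decarboxylase gene listed for basophils, was 5.07 above GFP-low monocytes in granulocytes. Jchain, the joining chain gene of plasma cells, was highest in GFP-low monocytes (8.18).

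A male donor for the array of Gfi1-deficient monocytes and female donors for the others could explain its low Xist and high Eif2s3y. Genes known to escape X inactivation were lower there than in GFP-low monocytes by a median log2 difference of -0.31, with Kdm6a at -0.85, Kdm5c at -0.48, Ddx3x at -0.30, Eif2s3x at -0.25 and Pbdc1 at -0.03. Against GFP-high monocytes these genes were also lower, from -0.17 for Kdm5c to -0.49 for Kdm6a. Granulocytes lay above Gfi1-deficient monocytes in Kdm6a, Kdm5c and Ddx3x. They lay below them in Eif2s3x (9.13 against 9.67) and Pbdc1 (6.71 against 8.34). The values of both heterozygous Gr1-low arrays go with the hypothesis, while those of granulocytes went both ways. The labels neither state nor exclude it.

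Carry-along of the chromosome region around the knock-in allele may alter neighbouring genes. Of the 40 measured genes nearest to Gfi1, 20 on each side, 1 was at least 2-fold apart between Gfi1-deficient and GFP-low monocytes (Arhgap24, 1.23). This does not exceed the upper hypergeometric limit of 3, given 153 of 8010 genes at least 2-fold apart. GFP-low monocytes carry 1 copy of the same allele, however, so a raised effect on the allele's own neighbours stays under 2-fold in this comparison. The count could hardly have shown a raised effect, which stays open. A lowered effect can exceed 2-fold there, and 0 of the 30 neighbours that lay at least 2-fold above the floor in GFP-low monocytes were at least 2-fold lower (limit 2, lowest value -0.38). This argues against a loss of 2-fold or more over several of these neighbours, while a smaller one stays open.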
